A study of Mus musculus with 12 samples.

How the data were processed

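Total RNA of 12 cultures of NIH-3T3 fibroblasts was profiled on 1-colour Illumina bead arrays after labelling with biotin, per the labels. The cells carried wild-type or E157D PPARG2 and had been given DMSO or 20 µM rosiglitazone for 24 h, which makes 4 groups of 3 arrays. The labels speak of 3 independent experiments, and whether each receptor was transduced once or several times is not given in the sources used here. The authors deposited, per the file headers, a signal intensity and a detection p-value for each of 45281 probes on each array, with no normalization between arrays. The detection p-values move in steps of 1 in 936, and the lowest intensity deposited was 107, so the intensities were not background-subtracted below 0. A separate table of the authors' processed intensity values has the same probes on a linear scale. Its method is not given in the sources used here, and each column ranked the probes as the raw column of the same array did, with medians from 172.5 to 178.1. It served only as an alternative.

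Intensities were background-corrected with normexp, with the mean and spread of the negative controls inferred from the detection p-values, an offset of 16 was added, and arrays were quantile-normalized and put on the log2 scale (neqc of limma 3.58.1, R 4.3.3). Because quantile normalization gives every array one distribution, a shift of all genes in one direction would not show. Probes detected at p under 0.05 on at least 3 arrays were kept, 18921 in all, of which 13894 were detected on all 12. Gene symbols came from the platform annotation, in which 34885 probes have 1 symbol, 18 several and 10378 none; 34807 were matched by gene number to a RefSeq table of the mouse assembly GRCm38.p6, used for names only, and no symbol changed. A probe without a symbol is unnamed here, not without a gene. Each gene was represented by its kept probe with the highest mean over all arrays, and the 2924 unnamed probes were kept under their own identifiers. Among the 3473 features called for rosiglitazone with the wild-type receptor, 1258 had further kept probes, which had the opposite sign for 172 and were themselves called for 5.

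A linear model with 4 group means was fitted with lmFit and eBayes, so all comparisons share an estimate of the spread with 8 residual and 3.9 prior degrees of freedom. The comparisons were rosiglitazone against DMSO with each receptor, E157D against wild-type in each treatment, the difference of the 2 responses, and the average response. Benjamini-Hochberg adjusted p under 0.05 made a call. Errors beside log2 changes are the standard errors of limma. Where a probe was below detection on all 3 arrays of a group, the change is given as at least N-fold. It is the detected group's mean against the mean of, per array, the higher of the probe's value and the lowest log2 value among detected probes, and list medians called at the floor use the same value. The size of the response was compared as the mean, over features called in the average response, of log2 values signed by its direction, with an exact permutation of receptor within treatment over 400 assignments.

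The 25 gene lists, the tests and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the 25 lists of a comparison, 125 tests in 5 comparisons. The rule took, for each comparison, the 12 largest rises and 12 largest falls among called genes with an established symbol whose arrays did not overlap between groups (not asked for the difference of responses), a separation that chance gives to 10% of genes. It added up to 4 called members of each list or, where none was called, the 2 with the smallest p, and 8 fixed genes of fat metabolism. The text names part of those.

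The replicate numbers were checked for pairing by the correlation of same-numbered arrays' deviations from their group means. Over the 3 pairs it was 0.129 to 0.239 for rosiglitazone with the wild-type receptor, above the limit of 0.1, so these numbers pair the arrays, from the data and not from the labels. In the other comparisons 1 or more pairs lay below 0.1. Over all groups, however, same-numbered arrays correlated at 0.017 to 0.255, and 11 arrays correlated best with arrays of their own number. These values point to a block in the other comparisons too, which the main fit leaves out. The fit with the number as a block moved the count for the paired comparison by less than 1.5 times. It moved others by more. Rosiglitazone with E157D went from 533 to 820, the receptors in DMSO from 146 to 233 and the difference of responses from 310 to 471.

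The pipeline was tested on simulated arrays with the real means and spreads of all 13006 features and known changes. For rosiglitazone with the wild-type receptor 14.9% of features changed by 0.5, 88.1% of those changed by 1 and 100% of those changed by 2 on the log2 scale were called. For the difference of responses these shares were 4.48%, 52.2% and 98.5%. In each simulation 67, 67 and 66 features were changed by 0.5, 1 and 2, with noise independent between features. For rosiglitazone with the wild-type receptor this gave 141 calls, where the real arrays gave 3473. The adjusted threshold is less strict with so many calls, so these shares do not give the power of the real comparisons. Alternatives covered the background correction, the offset (50), the scaling, the authors' values, the detection filter, the probe rule, the moderation, array weights, the groups in the fit, the replicate block and leaving out each array or replicate number. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.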

Results

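Gene expression was measured in NIH-3T3 cells, an established line of mouse embryonic fibroblasts, made to carry PPARG2 by a lentivirus. PPARG2 is the fat-cell isoform of PPARγ, a nuclear receptor that binds DNA and turns on genes of adipocyte differentiation and lipid storage. The cells expressed either the wild-type receptor or the mutant E157D, in which aspartate replaces a glutamate of the DNA-binding domain. Rosiglitazone, a thiazolidinedione agonist of PPARγ, was given at 20 µM for 24 h, and control cells received its vehicle DMSO. Each of the 4 groups held 3 arrays, 12 in all, and the labels describe 3 independent experiments. Each array carried 45281 probes, of which 16633 to 17924 (36.7% to 39.6%) were detected above the negative controls. Arrays of 1 group correlated at 0.988 to 0.994 across tested features, and no pair of arrays held identical values. The number of arrays limits the precision of every value given here. The question, from the title of the series, was what the E157D receptor does to transcription in these fibroblasts.

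The transgene itself could not be followed. The 3 probes named Pparg were below detection on all 12 arrays, with a lowest detection p of 0.12, so the arrays gave no measure of the amount of either receptor. Cd36, a fatty acid transporter and a known PPARγ target, was also not detected on any array and was not tested. In total 13006 features passed the detection filter, 10082 of them under a gene symbol. The first principal component held 47.4% of the variance and set the wild-type rosiglitazone arrays apart, and the next component held 14.6%.

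With the wild-type receptor, rosiglitazone raised genes of fat cells and of fat metabolism. Fgf21, a metabolic hormone, was at least 41.9-fold higher, and Cidec, which enlarges lipid droplets, was at least 24.3-fold higher; both were below detection in DMSO. The log2 change was 4.57 ± 0.36 (SE, n = 3 arrays per group) for Acaa1b, a peroxisomal thiolase, and G0s2, an inhibitor of fat breakdown, rose 16-fold (log2 SE 0.30). Gpat3 and Agpat2, enzymes of triglyceride synthesis, rose by 3.57 ± 0.18 and 3.40 ± 0.20. Adipoq, the hormone adiponectin, rose by 3.34 ± 0.15, Ephx2 by 3.28 ± 0.13 and S100a1 by 3.53 ± 0.14. Plin1, a coat protein of the adipocyte lipid droplet, was at least 6.22-fold higher, Atp2a3 at least 8.88-fold and Fabp4, the adipocyte fatty acid carrier, at least 1.74-fold. Ffar2, a receptor of short-chain fatty acids, rose by 4.24 ± 0.19 and was detected on 2 of the 3 DMSO arrays. Among the genes chosen in advance, Plin2 rose by 1.91 ± 0.18, Angptl4 by 1.48 ± 0.14 and Lpl by 1.15 ± 0.09, while Pdk4 differed by 0.24 ± 0.14 and did not pass (adjusted p = 0.237).

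**Figure D1:**
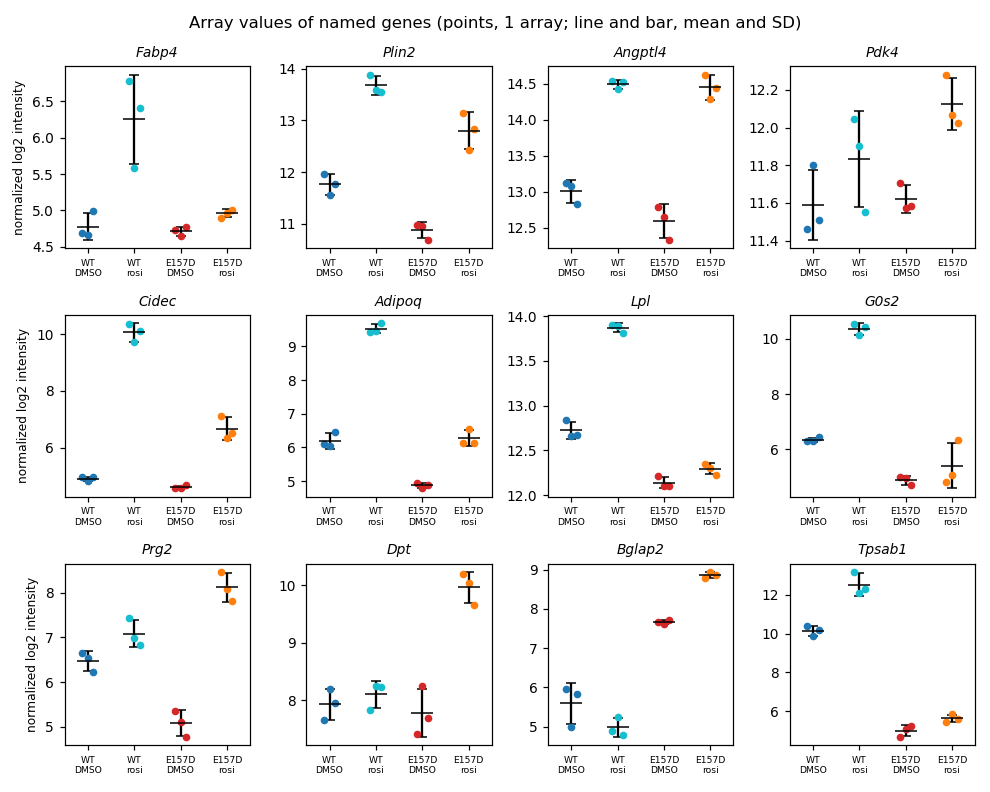
Normalized log2 intensity of 12 named genes, each panel with its own vertical axis. Points are arrays, and the line and bar are the mean and SD of the 3 arrays of a group (WT, wild-type PPARG2; rosi, rosiglitazone). Adipoq, Lpl and G0s2 are highest on the wild-type rosiglitazone arrays, Angptl4 lies at the same height with both receptors under rosiglitazone, and Dpt and Bglap2 are highest on the E157D rosiglitazone arrays.

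Of the 13006 features, 3473 changed at a Benjamini-Hochberg adjusted p under 0.05 with limma, 1597 higher and 1876 lower. A change of at least 2-fold was seen for 294 of the higher and 253 of the lower ones. In the list of PPAR target genes, 17 of 21 measured members rose and 0 fell, also when adjusted over the list alone, with a median log2 change of 1.47, or 1.43 with undetected groups raised to the detection floor. All 24 measured genes of fatty acid oxidation rose, 24 adjusted over the list alone, with a median of 0.98. Examples are Acot2 (2.24 ± 0.18), a mitochondrial thioesterase, Crat (1.59 ± 0.20), which transfers acetyl groups to carnitine, and Acaa2 (1.48 ± 0.16). Of 11 adipocyte markers 8 rose, 9 adjusted over the list alone, where 1 also fell; the median was 1.42, or 1.15 with undetected groups at the floor. Lipid droplet and triglyceride synthesis had 16 of 22 members higher and 1 lower (17 and 1 adjusted over the list alone). In the mitochondrial respiratory chain 21 of 23 genes rose, 22 adjusted over the list alone, with a smaller median of 0.59. Cycs, which encodes cytochrome c, rose by 2.03 ± 0.19 and Cyc1 by 1.21 ± 0.10. The ER stress and amino acid response list had 14 of 23 genes higher, 16 adjusted over the list alone. Its leading members were Trib3 (2.14 ± 0.11), a pseudokinase induced by stress, Chac1 (1.81 ± 0.16), Dnajb9 (1.59 ± 0.14) and Ddit3 (1.52 ± 0.15), the transcription factor CHOP. These 6 lists passed camera against the other genes with its preset correlation, at adjusted p from 1.08e-19 for fatty acid oxidation to 3.45e-08 for ER stress, and also with an estimated correlation. In the NRF2 oxidative stress response 9 of 17 genes rose and 1 fell (11 and 1 adjusted over the list alone), led by Hmox1 (1.91 ± 0.28) and Cat (1.25 ± 0.18), with adjusted p = 0.0573 with an estimated correlation. In glycolysis and hypoxia response 7 of 22 rose and 1 fell (9 and 1 adjusted over the list alone), and adjusted p = 0.193 with an estimated correlation. Synthesis of fatty acids (2 of 15 higher, 1 adjusted over the list alone) and of cholesterol (0 of 17 in either direction, 0 adjusted over the list alone) did not pass, at adjusted p = 0.425 and 0.408. Of 3 brown adipocyte markers 2 rose, 2 adjusted over the list alone, with adjusted p = 0.0836 with an estimated correlation.

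Among the largest falls with the wild-type receptor, Ogn, a small leucine-rich proteoglycan, had a log2 change of -2.66 ± 0.38, Cemip, which takes part in hyaluronan breakdown, -2.43 ± 0.27, and the cytokine Il33 -2.38 ± 0.32. Itgbl1 (-2.32 ± 0.33), Mfap5 (-2.20 ± 0.19), a microfibril protein, Saa3 (-2.19 ± 0.34), an acute phase protein, and Igf2 (-1.91 ± 0.45), a growth factor, followed. Of 26 genes of extracellular matrix and remodelling 18 fell and 2 rose (19 and 2 adjusted over the list alone), among them Lum (-1.61 ± 0.32), Fn1 (-1.45 ± 0.22) and Dcn (-1.43 ± 0.17). The call of this list was lost with an estimated correlation, at adjusted p = 0.121. Of 21 contractile genes responsive to TGF-beta, SRF and YAP 11 fell and 0 rose (12 and 0 adjusted over the list alone), led by Tgfbi (-1.60 ± 0.14) and Ccn2 (-1.53 ± 0.19), with adjusted p = 0.0575 with an estimated correlation. Inflammatory cytokines and NF-kB targets had 8 of 17 genes lower, 9 adjusted over the list alone, and this list passed with both correlations (adjusted p = 0.000489 preset and 0.022 estimated). Interferon response genes had 7 of 15 lower, 10 adjusted over the list alone, with adjusted p = 0.115 with an estimated correlation. Preadipocyte genes (7 of 15 lower and 2 higher, 8 and 2 adjusted over the list alone), p53 response genes (5 of 15 lower and 1 higher, 6 and 2 adjusted over the list alone) and DNA replication genes (5 of 24 lower and 1 higher, the same adjusted over the list alone) did not pass as lists, at adjusted p = 0.0937, 0.214 and 0.147. Nor did angiogenic factors (6 of 12 lower and 2 higher, 7 and 3 adjusted over the list alone), immediate early genes (3 of 15 lower and 2 higher, 4 and 2 adjusted over the list alone) or nuclear receptors (2 of 14 higher and 1 lower, the same adjusted over the list alone), at adjusted p = 0.214, 0.512 and 0.136. The markers of other cell types did not pass either: 1 of 3 leukocyte, 0 of 4 skeletal muscle, 1 of 6 osteoblast and 1 of 4 epithelial or endothelial markers fell and 0 rose, the same adjusted over the list alone, at adjusted p = 0.096, 0.496, 0.208 and 0.43. With each array scaled to its median in place of quantile normalization, 55.9% of the calls were higher ones against 46.0% as normalized here.

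With the E157D receptor fewer genes were called for the same drug, and genes of fatty acid oxidation were among those that rose. The adjusted threshold is stricter with fewer calls, so the counts alone do not measure a difference between the receptors. Ephx2, an epoxide hydrolase, rose by 3.94 ± 0.13, Acaa1b by 3.39 ± 0.36 and Itgad, an integrin subunit of leukocytes, by 2.66 ± 0.21. Fgf21 was at least 12.5-fold higher, Prg2, a granule protein of eosinophils, at least 6.44-fold, Vsir at least 4.32-fold and Cidec at least 2.35-fold, each below detection in DMSO. Dpt, a matrix protein, rose by 2.18 ± 0.22, Ubd by 2.15 ± 0.17 and Acsbg1, an acyl-CoA synthetase, by 2.06 ± 0.13. The droplet genes Plin2 (1.93 ± 0.18), Pnpla2 (1.62 ± 0.14), the main triglyceride lipase, and Plin4 (1.37 ± 0.15) rose, as did Angptl4 (1.86 ± 0.14), and Adipoq was at least 1.79-fold higher. Lpl differed by 0.16 ± 0.09 (adjusted p = 0.415) and Pdk4 by 0.50 ± 0.14 (adjusted p = 0.0759), and Fabp4 was below detection in both groups. The genes that fell included Saa3 (-1.75 ± 0.34), Ogn (-1.73 ± 0.38), Mfap5 (-1.48 ± 0.19), Tnfrsf11b (-1.38 ± 0.12), a decoy receptor of bone, and Ccn2 (-1.26 ± 0.19). The calls of Saa3 and Ogn ended when some single arrays were left out, at adjusted p up to 0.0534 and 0.11. These were E157D rosiglitazone 3 for Saa3 and E157D rosiglitazone 1 and 3 and DMSO 2 and 3 for Ogn.

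In all, 533 features changed, 300 higher and 233 lower, of which 87 and 37 by at least 2-fold. Fatty acid oxidation had 12 of 24 members higher and 0 lower, and 17 and 1 adjusted over the list alone, with a median of 0.51. Acaa2 rose by 1.29 ± 0.16, Hadhb by 0.93 ± 0.15 and Acadl by 0.90 ± 0.13, all enzymes of the mitochondrial spiral. PPAR target genes had 8 of 21 higher (11 adjusted over the list alone, median 0.39), and the respiratory chain 2 of 23 (7 adjusted over the list alone, median 0.23). These 3 lists passed camera with the preset and with an estimated correlation (adjusted p = 0.0319 for each with an estimated correlation). Lipid droplet genes had 7 of 22 higher (7 higher and 1 lower adjusted over the list alone), with adjusted p = 0.0936 with an estimated correlation. Of adipocyte markers 2 of 11 rose, 2 adjusted over the list alone, and of ER stress genes 1 of 23, Trib3 (0.47 ± 0.11), 1 adjusted over the list alone; adjusted p = 0.167 and 0.181 with an estimated correlation. The call of Trib3 ended with median scaling and without any of the 6 arrays but E157D DMSO 3, at adjusted p up to 0.126. Contractile genes had 4 of 21 lower (4 lower and 1 higher adjusted over the list alone) and interferon response genes 2 of 15 (3 adjusted over the list alone), with adjusted p = 0.167 and 0.181 with an estimated correlation. Matrix genes (2 of 26 lower), inflammatory genes (2 of 17 lower), NRF2 genes (3 of 17 higher), glycolysis (2 of 22 higher and 1 lower), cholesterol synthesis (0 of 17) and leukocyte markers (0 of 3) passed camera with the preset correlation alone, at adjusted p from 0.167 to 0.325 with an estimated correlation. Adjusted over the list alone these counts were 2 lower, 2 lower, 3 higher and 1 lower, 6 higher and 2 lower, 0, and 2 lower. Without 1 array the count of 533 dropped to between 243 and 300 for each of E157D DMSO 1, 2 and 3 and E157D rosiglitazone 1 and 3. With median scaling 77.9% of the calls were higher ones against 56.3% here, and the count with background left uncorrected was 928.

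**Figure D2:**
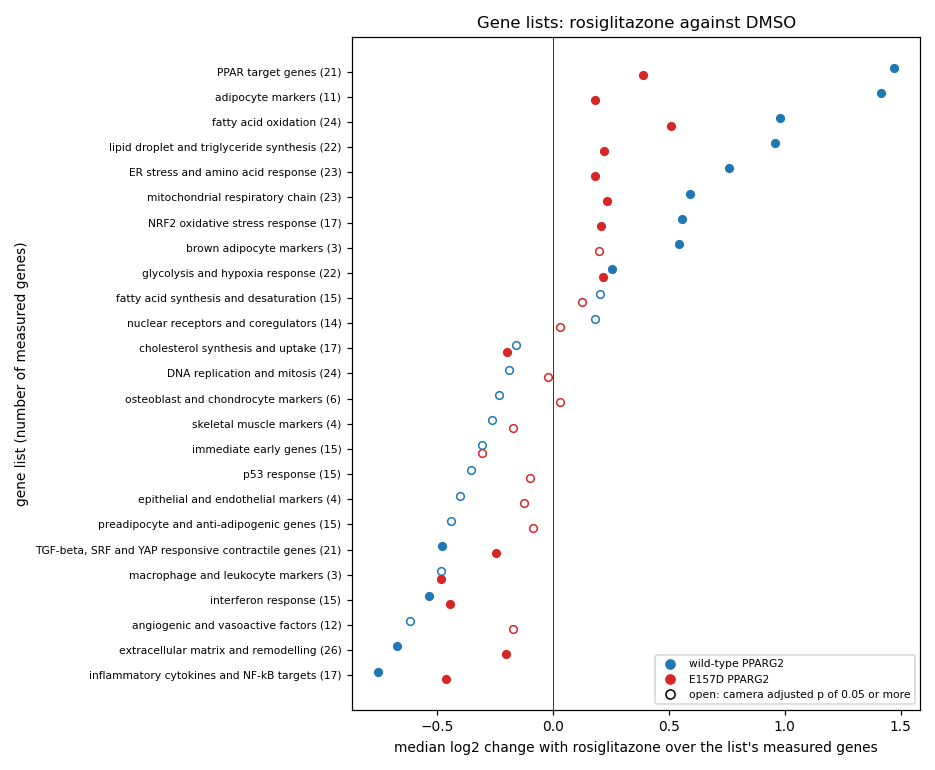
Median log2 change with rosiglitazone over the measured genes of each of 25 gene lists (vertical axis, number of genes in parentheses), for the wild-type (blue) and the E157D receptor (red). Filled points passed camera with its preset correlation at an adjusted p under 0.05. The medians of PPAR target genes were 1.47 and 0.39, and those of fatty acid oxidation 0.98 and 0.51.

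The responses to rosiglitazone with the 2 receptors, which share no arrays, overlapped. There were 202 features higher with both, where independent lists of these lengths would share 36.8, and 207 lower with both, against 33.6. Another 8 moved in opposite directions. None of the 4 groups held cells without a transduced receptor. A response shared by both receptors can therefore not be told apart from one that needs neither. Across all tested features the log2 changes correlated at r = 0.582 and rho = 0.531, where genes are not independent replicates. Over the 3628 features changed by rosiglitazone on average of the receptors, 1718 higher and 1910 lower, the mean change in the direction of the response was 0.68 on the log2 scale with the wild-type and 0.38 with the E157D receptor, 55.3% as much. The score behind it rose from -0.65 ± 0.03 (SD, n = 3) to 0.03 ± 0.08 with the wild-type and from -0.74 ± 0.01 to -0.36 ± 0.07 with E157D. The two-sided exact permutation test of receptor within treatment for the difference of -0.31 does not decide it (p = 0.1, over 400 assignments). The scores also differed between the receptors in DMSO, in the same direction, so that all 40 assignments that kept the rosiglitazone groups or their mirror gave a difference as large, whatever the DMSO groups, and p could not be lower; none of the others did. Of the average calls, 63.7% were higher ones with median scaling against 47.4% here.

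A test of the difference itself was passed by 310 features, 115 with a higher and 195 with a lower response in E157D cells. Higher and lower refer to the signed log2 change, so a weaker fall counts as a higher response. The difference of the log2 changes, E157D against wild-type, was -3.57 ± 0.20 for S100a1, a calcium-binding protein, -3.48 ± 0.42 for G0s2, -3.28 ± 0.28 for Agpat2, -3.11 ± 0.27 for Cidec and -2.49 ± 0.26 for Gpat3. Adipoq differed by -1.94 ± 0.21 and Lpl by -0.99 ± 0.13. Ffar2 (-3.88 ± 0.27), Atp2a3 (-3.56 ± 0.28), Plin1 (-2.94 ± 0.23), Sh3tc2 (-2.51 ± 0.24) and Aqp7 (-2.20 ± 0.34), a glycerol channel, were below detection on all 6 E157D arrays, so that these sizes depend on the background. G0s2, Cidec and Adipoq were below detection in 1 or more groups too. The same holds for Cyp4b1 (-2.39 ± 0.36) and its neighbour in sequence Cyp4b1-ps2 (-3.15 ± 0.25), whose probes may share transcripts and are uncertain. Plin2 (0.02 ± 0.25), Angptl4 (0.37 ± 0.20) and Pdk4 (0.26 ± 0.20) did not pass, at adjusted p = 0.982, 0.394 and 0.595, and neither did Fabp4 (-1.23 ± 0.33, adjusted p = 0.0772).

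**Figure D3:**
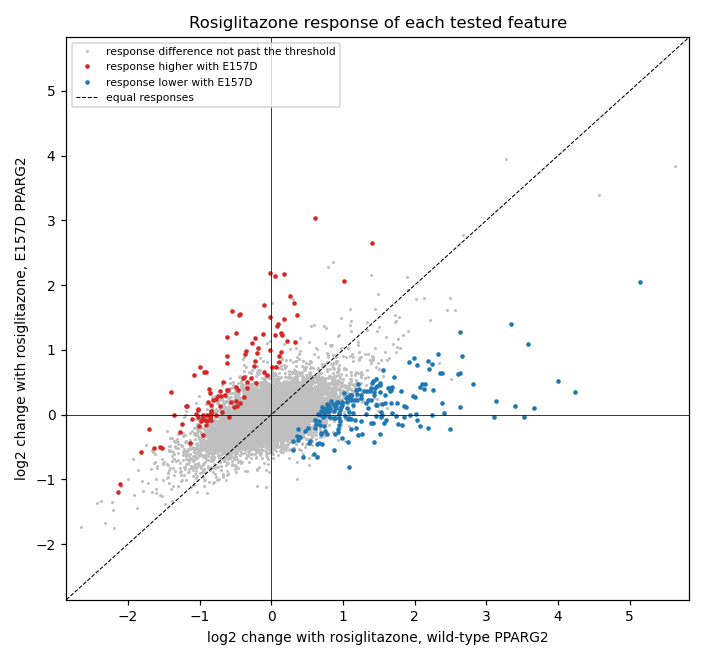
Log2 change with rosiglitazone of each of the 13006 tested features with the wild-type (horizontal axis) and the E157D receptor (vertical axis). Blue and red points are the 195 features with a lower and the 115 with a higher response in E157D cells at an adjusted p under 0.05. The response is the signed log2 change, so a weaker fall counts as higher. Grey points are the others, and the broken line marks equal responses. Most blue points lie right of the vertical zero line and below the broken line.

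Of the 310 features, 192 rose with the wild-type receptor and had a weaker response with E157D, and 171 of these were not called in E157D cells. There were 70 that fell with the wild-type receptor and fell less or rose with E157D, and 61 of these were not called in E157D cells. A group of 49, which shares 7 features with the 70, rose in E157D cells with a higher response than in wild-type cells; 37 of the 49 were not called with the wild-type receptor, the 7 fell there and 5 rose. In rosiglitazone 47 of the 49 were higher in E157D than in wild-type cells and 2 were lower, while in DMSO 9 were higher and 4 lower. Prg2, below detection in E157D DMSO cells, had a difference of 2.42 ± 0.30, Ccl9, a chemokine, of 2.16 ± 0.35, Dpt of 2.00 ± 0.31, Ccdc3 of 1.99 ± 0.35, Aldh3a1, an aldehyde dehydrogenase, of 1.98 ± 0.31 and Sncg of 1.80 ± 0.31. Bglap2 (1.81 ± 0.30) and Bglap (1.36 ± 0.15), near-identical genes for osteocalcin that their probes may not separate, were below detection on the wild-type rosiglitazone arrays. Vgll3 (1.57 ± 0.17), Gria1 (1.70 ± 0.20) and Apol9a (1.60 ± 0.21) fell with the wild-type receptor and rose with E157D.

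By list, adipocyte markers had 6 of 11 members with a lower response (7 lower and 1 higher adjusted over the list alone, median -1.23, or -0.99 with undetected groups at the floor), fatty acid oxidation 5 of 24 (15 adjusted over the list alone, median -0.56), lipid droplet genes 6 of 22 (8 lower and 1 higher adjusted over the list alone, median -0.42) and the respiratory chain 2 of 23 (9 adjusted over the list alone, median -0.34). Of the ER stress genes 6 of 23 had a lower response (9 adjusted over the list alone, median -0.50), among them Trib3 (-1.67 ± 0.16), Chac1 (-1.44 ± 0.23) and Dnajb9 (-1.41 ± 0.20). PPAR target genes had 7 of 21 lower (11 lower and 1 higher adjusted over the list alone), with a median of -0.69 that turned to 0.02 over the members detected on all 12 arrays. These 6 lists passed camera with both correlations, with adjusted p from 0.0222 to 0.048 with an estimated correlation. Extracellular matrix genes had 1 of 26 with a higher response (3 adjusted over the list alone, median 0.39), with adjusted p = 0.19 with an estimated correlation. The median change of this list was -0.67 with the wild-type receptor and -0.20 with E157D, a weaker fall. Without 1 array the count of 310 dropped to between 180 and 205 for WT DMSO 2 and 3, WT rosiglitazone 1, E157D DMSO 1, 2 and 3 and E157D rosiglitazone 2. It was 194 with median scaling, 657 with no background correction and 678 from the authors' processed values.

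In cells given DMSO for 24 h, Tpsab1, a tryptase of mast cells, was at least 26.3-fold lower with E157D than with the wild-type receptor and Itgad had a log2 difference of -4.64 ± 0.21. Plin4, a lipid droplet protein, differed by -2.95 ± 0.15, Cyp2c70 by -2.81 ± 0.11, Acaa1b by -2.41 ± 0.36, Chst1, a sulfotransferase, by -2.37 ± 0.15 and Col18a1, a basement membrane collagen, by -1.99 ± 0.14. Lcn2, an iron-carrier-binding protein, differed by -2.41 ± 0.24, and Mycl was at least 3.7-fold lower. Serpinb9f and Serpinb9g, near-identical protease inhibitors whose probes are uncertain, were at least 6.6-fold and 5.84-fold lower. Rarres2, the adipokine chemerin, differed by -2.37 ± 0.17, though another of its probes gave 0.03. Adipoq was at least 1.69-fold lower and Aqp7 at least 1.86-fold, while Angptl4 (-0.42 ± 0.14), Pdk4 (0.03 ± 0.14) and, below detection in both groups, Cidec and Fabp4 did not pass. Lpl (-0.59 ± 0.09) and Plin2 (-0.89 ± 0.18) passed but lost the call with median scaling and without single arrays, Lpl without E157D DMSO 2 or 3 (adjusted p up to 0.0564) and Plin2 without any 1 of the 6 arrays (adjusted p up to 0.169). Higher in E157D cells were the matrix genes Lum (2.29 ± 0.32) and Mgp (2.03 ± 0.21), an inhibitor of calcification, as well as Bglap2 (2.07 ± 0.21), Sncg (1.75 ± 0.22) and Mrvi1 (2.27 ± 0.27), another probe of which gave -0.28.

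In DMSO 146 features differed, 55 higher and 91 lower in E157D cells, with 22 and 44 by at least 2-fold. Of PPAR target genes 5 of 21 were lower (8 lower and 1 higher adjusted over the list alone, median -0.29, or -0.17 with undetected groups at the floor), of lipid droplet genes 4 of 22 (9 lower and 1 higher adjusted over the list alone, median -0.33) and of adipocyte markers 3 of 11 (4 adjusted over the list alone, median -0.31, or -0.15 at the floor). For each of these 3 lists adjusted p = 0.091 with an estimated correlation, and none of the 25 lists passed with it, where 11 passed with the preset one. Contractile genes had 2 of 21 higher (10 adjusted over the list alone, median 0.35), with adjusted p = 0.102 with an estimated correlation. Of the macrophage and leukocyte markers only 3 of the 14 with a probe were measured, and 0 of these passed, 0 adjusted over the list alone (adjusted p = 0.422). Among the 91 lower features 53 rose with rosiglitazone in wild-type cells and 15 fell, where independent lists would share 11.2 of the former. Among the 55 higher ones 25 fell with rosiglitazone and 5 rose, where 7.93 would be shared in the former. Both comparisons use the wild-type DMSO arrays. Unchanged groups simulated against shared arrays gave a correlation of 0.50 and a covariance of 0.0156 between the changes, and the observed values were -0.181 and -0.024. Without 1 array the count of 146 dropped to between 77 and 97 for WT DMSO 1, 2 and 3 and E157D DMSO 2 and 3. With median scaling 55.6% of the calls were higher against 37.7% here, the median of all features moving to 0.12.

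Under rosiglitazone the receptors differed at 2571 features, 1367 higher and 1204 lower in E157D cells, with 218 and 263 by at least 2-fold. The log2 difference was -6.88 ± 0.26 for Tpsab1, -4.94 ± 0.30 for G0s2, -4.91 ± 0.14 for S100a1, -3.94 ± 0.20 for Agpat2, -3.40 ± 0.19 for Cidec and -3.26 ± 0.15 for Adipoq. On E157D rosiglitazone arrays 1 and 2 G0s2, at 4.82 and 5.07, lay below the lowest detected values (5.35 and 5.39), so its size depends on the background. Tpsab1, at 5.47 to 5.84 on the E157D rosiglitazone arrays, lay just above the lowest detected values (5.35 to 5.46). The size of its difference depends on the background too. Ffar2 was at least 18.6-fold lower, Aqp7 at least 9.91-fold, Plin1 at least 6.48-fold and Fabp4 at least 1.81-fold. Lpl (-1.58 ± 0.09) and Plin2 (-0.88 ± 0.18) were lower, and Angptl4 (-0.04 ± 0.14, adjusted p = 0.868) and Pdk4 (0.29 ± 0.14, adjusted p = 0.185) did not pass. Bglap2 was at least 10.2-fold higher, and Sncg (3.54 ± 0.22), Mgp (3.02 ± 0.21), Lum (2.92 ± 0.32), Ogn (2.71 ± 0.38), Ramp2 (2.71 ± 0.22), a receptor partner for adrenomedullin, and Vgll3 (2.42 ± 0.12) were higher too. Of the features that differed in DMSO, 75 were lower and 48 higher in E157D cells under both treatments, and 3 changed direction.

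By list, 9 of 11 adipocyte markers were lower and 1 higher in E157D cells under the drug (9 and 1 adjusted over the list alone, median -1.58, or -1.35 with undetected groups at the floor), 14 of 21 PPAR target genes were lower and 1 higher (14 and 2 adjusted over the list alone, median -1.29, or -0.92 at the floor), and 18 of 24 fatty acid oxidation genes were lower (20 adjusted over the list alone, median -0.81). Lipid droplet genes had 14 of 22 lower and 1 higher (15 and 1 adjusted over the list alone) and the respiratory chain 17 of 23 lower (19 adjusted over the list alone). These 5 lists passed with both correlations. Of the extracellular matrix genes 17 of 26 were higher and 1 lower (19 and 1 adjusted over the list alone, median 0.62), among them Dcn (1.40 ± 0.17), and of the contractile genes 14 of 21 were higher (16 higher and 1 lower adjusted over the list alone, median 0.59), among them Actg2 (1.64 ± 0.15) and Myl9 (1.66 ± 0.25). Their calls were lost with an estimated correlation, at adjusted p = 0.108 and 0.0562. ER stress genes had 11 of 23 lower and 1 higher (12 and 1 adjusted over the list alone), with adjusted p = 0.0583 with an estimated correlation, and cholesterol synthesis 8 of 17 lower (8 adjusted over the list alone), with adjusted p = 0.108 with an estimated correlation. The count of 2571 dropped to 1626 without WT rosiglitazone 1. With median scaling, which moved the median of all features to 0.17, 77.4% of the calls were higher against 53.2% here.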

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

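The tests over splits of the arrays and the search for other mast cell and eosinophil markers were set before their results were seen, and the other tests of this part were chosen after. What brought the results here is the test of the difference between the responses to rosiglitazone with the 2 receptors, except for the features lower with E157D in DMSO, which were taken up after their values were seen. It called 310 features. When the receptor labels were reassigned within each treatment, 8 of 100 assignments, the real one included, gave as many, with 1502 in the highest other one. The other 7 all kept the rosiglitazone arrays of each receptor together, with the receptor labels as they were or exchanged. The 92 assignments that mixed the rosiglitazone arrays called 0 features with limma. An assignment with several times the real count points to a structure of the samples, here the difference between the receptors under rosiglitazone. That difference enters the count whenever the rosiglitazone groups are kept or exchanged. This test can therefore not decide on chance for the 310, and chance is not excluded. The average response of 3628 features was reached by 1 of 100 sampled assignments, the real one, a share under 0.05. The highest other gave 2273 with the E157D arrays mixed between treatments, so this count by itself does not show a response with both receptors. For the 4 pairwise counts the 10 splits of 6 arrays are too few for a share under 0.05. As many features came from 1 split, the real one, for rosiglitazone with the wild-type receptor (3473, highest other 2), with E157D (533, highest other 0), and for the receptors in DMSO (146, highest other 0) and in rosiglitazone (2571, highest other 0).

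Among the gene lists the median difference of responses, E157D against wild-type, was -0.69 for PPAR target genes, -1.23 for adipocyte markers, -0.42 for lipid droplet genes, -0.56 for fatty acid oxidation, -0.50 for ER stress, -0.34 for the respiratory chain, -0.82 for brown adipocyte markers and -0.30 for the NRF2 response. It was 0.39 for extracellular matrix, 0.27 for contractile genes, 0.37 for inflammatory genes, 0.23 for interferon response and 0.39 for osteoblast and chondrocyte markers, the last turning to -0.01 with no detection filter. The median of PPAR target genes changed sign over the members detected on all 12 arrays. The call was lost for brown adipocyte markers and inflammatory genes (adjusted p = 0.0869 each), NRF2 and osteoblast genes (0.105 each), contractile genes (0.141), matrix genes (0.19) and interferon genes (0.335) with an estimated correlation.

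Of the named genes, those with a lower response in E157D cells were Ffar2 (-3.88), S100a1 (-3.57), Atp2a3 (-3.56), G0s2 (-3.48), Agpat2 (-3.28), Cyp4b1-ps2 (-3.15), Cidec (-3.11), Plin1 (-2.94), Lims2 (-2.72), Sh3tc2 (-2.51), Gpat3 (-2.49), Cyp4b1 (-2.39), Aqp7 (-2.20) and Adipoq (-1.94). Smaller ones were Crat (-1.68), Trib3 (-1.67), Egln3 (-1.63), Acot2 (-1.45), Chac1 (-1.44), Dnajb9 (-1.41), Cycs (-1.26), Cpt1b (-1.16), Ddit3 (-1.02), Lpl (-0.99), Pank1 (-0.94), Vegfa (-0.85), Decr1 (-0.83), Gsta4 (-0.82), Cyc1 (-0.74), Slc25a1 (-0.72) and Sod2 (-0.63). A higher response was seen for Prg2 (2.42), Ccl9 (2.16), Abcb4 (2.09), Dpt (2.00), Ccdc3 (1.99), Aldh3a1 (1.98), Bglap2 (1.81), Sncg (1.80), Spon2 (1.75), Gria1 (1.70), Apol9a (1.60), Vgll3 (1.57), Bglap (1.36), Ifit2 (1.06), Tnc (0.89) and Vcam1 (0.75). Other probes of Tnc gave -0.59 and -0.19 and another of Vcam1 gave -0.33. All are fitted differences of signed log2 changes, so a higher response can be a weaker fall. For genes below detection in a group they include signals at background. In leaving out each of the 12 arrays in turn, 34 of these 47 genes kept the call each time. The call was lost in 11 of the 12 fits for Cpt1b, Sod2 and Vcam1, in 10 for Abcb4 and Decr1, in 9 for Ifit2, in 8 for Cycs, Gsta4, Tnc and Vegfa, in 7 for Pank1, in 5 for Ddit3 and in 2 for Slc25a1, with adjusted p up to 0.111.

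One pattern is the group of 49 features that rose in E157D cells with a higher response than in wild-type cells. They make up 15.8% of the features called in the difference, above the 5% of false calls that a response only scaled down would allow, which argues against a uniformly weaker E157D response as the whole account. The share comes from the calls that define the pattern, so it is no separate test. With median scaling their median difference was 1.305 (median SE 0.251) against 1.292 (0.211) with quantile normalization, so the size was alike with both. The 49 were selected on the quantile-normalized values of the same arrays, so this does not exclude quantile normalization as a source. The size depends on the background correction and the values used: the median was 0.75 with the authors' values and 0.76 with no background correction, where 48 of the 49 kept the sign. The scaled median was chosen as the test after another measure came out undecided: 37 of the 49 (75.5%) kept the call with median scaling, and all 49 kept the sign. A difference between the cell populations that were transduced with each receptor cannot be told apart from an effect of E157D for these 49, since the labels describe no independent transductions.

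A related pattern is the 192 features whose rise was weaker with E157D. A lower amount of E157D receptor may account for it and cannot be told apart from weaker activity per receptor, because 0 of the 12 arrays had a Pparg probe detected.

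The remaining pattern is the 91 features lower with E157D in DMSO. Activity of the wild-type receptor without added ligand may account for part of them: 53 also rose with rosiglitazone in wild-type cells, where independent lists would share 11.2, although the shared DMSO arrays push the other way. For the 91 a difference between the transduced populations stays open, for the same reason as above. Among them are granulocyte genes, singled out after their values were seen: Tpsab1, at least 26.3-fold lower, and Prg2, at least 2.05-fold lower, both below detection in E157D DMSO cells. Mast cells or eosinophils in the wild-type cultures were tested with 17 other marker genes listed beforehand, 15 of them on the array. Of these 0 were detected on all 3 wild-type DMSO arrays, which argues against such cells. In wild-type cells the log2 value of Tpsab1 was 9.89 to 10.38 on the DMSO arrays and 12.09 to 13.19 on the rosiglitazone arrays.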

How the results depend on the processing

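The alternatives were chosen before the data were examined, and a count is called kept here when it stayed within 1.5 times. The direction of the difference in response size was kept throughout (-0.22 to -0.42), and its permutation p, held up by the receptor difference in DMSO, is no measure of it. Under the settings other than leaving out arrays, 327 of the 408 values of named genes and 65 of the 125 list medians kept their direction and their side of the threshold, and under leaving out arrays 239 and 103 did. Over all settings gene calls were lost 806 times and gained 84 times, and list calls were lost 108 times and gained 38 times. Reversed were the osteoblast list with no detection filter, to -0.032 between receptors in rosiglitazone and to -0.006 in the difference of responses, and the PPAR target list in the difference of responses over probes detected on all 12 arrays, to 0.019; fewer or more members then enter the median. With the replicate number as a fixed block the counts were 820 for rosiglitazone with E157D, 233 between receptors in DMSO and 471 for the difference of responses, and with a random block that in DMSO was 229. With no background correction, the authors' processed values, and trend and robust moderation, rosiglitazone with E157D gave 928, 867 and 892 and the difference of responses 657, 678 and 611. For the latter median scaling gave 194. Between receptors in DMSO the count was 229 with the authors' values, 233 with trend and robust moderation, 227 with an offset of 50, 240 with array weights and 88 with only the compared groups in the fit. The cause was not tested, apart from the smaller number of arrays in the last. Leaving out single arrays or all 4 arrays of a replicate number, which leaves fewer arrays, gave 1460 to 3186 for rosiglitazone with the wild-type receptor, 52 to 442 with E157D, 24 to 116 between receptors in DMSO, 1050 to 2285 in rosiglitazone, 24 to 306 for the difference of responses and 1521 to 3575 for the average response. Slide as a block was not run, since no slide barcodes are given, and lists have no value with a random block, which camera does not take. Signal over background limits the genes detected on few arrays.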

Other observations

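The rise of the ER stress and amino acid response genes with rosiglitazone raised a hypothesis, tested only after the values were seen. It was that 20 µM rosiglitazone may act on these genes without the DNA-binding domain of the receptor, in which case they would rise alike with both receptors present in equal amounts. The median difference of their responses was -0.497 on the log2 scale, past the threshold with both correlations. With the wild-type receptor 14 of 23 genes rose (median 0.76), and with E157D 1 of 23 (median 0.18). An action that needs no receptor, alike in both cell populations, would not depend on receptor amounts. These values argue against such an action as the whole account. An action through the receptor without DNA binding is left open. The amounts were not measured, and it would also be weaker with less E157D receptor. The condition of equal amounts was added after the result was seen. A difference between the transduced populations, also in an action that needs no receptor, stays open too.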
